A study of Rattus norvegicus with 18 samples.

How the data were processed

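Gene expression was measured in total RNA of rat hippocampus on 18 Affymetrix oligonucleotide arrays, 1 per sample. The labels give each sample a diet (alcohol, isocaloric or control) and a training state (trained in a procedure abbreviated CFC, or naive). The series concerns learning in rats exposed to alcohol before birth. The labels do not spell out CFC, and the time between training and tissue collection is not given in the sources used here. Each sample was placed in 1 of 6 groups by its description: 4 alcohol trained, 4 alcohol naive, 4 isocaloric trained, 2 isocaloric naive, 2 control trained and 2 control naive arrays. The labels do not say that replicates came from separate animals, so each p-value measures the spread between these samples, which may be partly technical. Nor do they say which samples shared a litter. Littermates share an exposure before birth, so samples of the same litter would not be independent replicates of a diet. The diet p-values do not account for this.

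The values deposited by the authors are 1 intensity per probe set and array on a linear scale. MAS5, the Affymetrix summary algorithm, is named for 2 of the samples in the submitters' processing notes, and for the other samples the algorithm is not given in the sources used here. On every array the mean after trimming 2% of values at each end was close to 150, which shows a common scaling to that level. In these 2 samples, control naive replicate 1 and control trained replicate 2, 100% of values were written with at most 6 digits, against 3.10% to 3.67% on the other arrays. These 2 arrays were therefore treated as a possible technical batch, which held control-diet samples alone. No batch term was fitted, and the comparisons with the control diet were also run without them. That fit leaves 1 array in each control group, control naive replicate 2 and control trained replicate 1. A lone array adds no spread of its own, so counts in such a fit rest on the spread of the other groups. A higher count in it does not show a stronger effect of diet. Scaling of all arrays to a shared level can hide a change of total RNA and can make a broad one-sided shift look smaller. No genome coordinates were used here.

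Of 15923 probe sets, 57 were Affymetrix controls. In the platform annotation 12789 probe sets had 1 gene symbol, 312 had several and 2822, controls included, had none. By gene ID, 12754 of the single-symbol probe sets matched a RefSeq gene table, with 0 symbols changed, and the other 35 kept the annotation's symbol. They covered 10412 genes. Probe sets with several symbols or none were tested but not named.

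Signal was analysed as log2(value + 6.06), the constant being the 10th percentile of all values, so that fold changes of dim probe sets are understated. Probe sets whose mean level lay under the 40th percentile were left out, as were the Affymetrix controls, and 9520 were tested. limma 3.58.1 in R 4.3.3 was run with lmFit on the 6 group means, which share 1 estimate of the spread over all 18 arrays, and eBayes with a trend on mean level. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. An averaged diet comparison is the mean of the differences in trained and in naive samples. The averaged training comparison weights the 3 diets equally. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

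Gene lists for neuronal, metabolic and stress functions and for the cell types and neighbouring tissues that a hippocampal dissection could hold were fixed in advance. Each list with at least 3 measured members, 27 in all, was tested with limma's camera at an inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean) and Benjamini-Hochberg adjustment over the lists. A list of blood cell markers had 1 measured member and was not tested. Camera was repeated with the correlation estimated for each list. Members past the threshold are counted over all probe sets tested and, separately, adjusted over the list alone.

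The named genes followed a rule. For each averaged comparison these were the 12 largest rises and 12 largest falls among single-symbol probe sets past the threshold, and for each other comparison the 5 largest of each. Where fewer passed in a direction, up to 5 (averaged comparisons) or 3 (others) with the smallest p were named as values that did not pass. Members of the lists past the threshold, the 4 members with the smallest p of each list past its own threshold, and Gap43, Elavl4, Bdnf, Arc, Fos, Egr1, Homer1, Grin1, Grin2b, Gria1 and Camk2a were added where measured. Fos did not pass the filter on low values. Placeholder symbols were not named. Among the ranked rises and falls, a gene with several probe sets is given by the one with the smallest p. List members and the genes added by name are given by the one with the highest mean over all arrays. For these, a gene that did not pass could have another probe set that did. Named genes outside this rule are marked as chosen after their values were seen. The rule, the groups, the tests and the alternatives were set before the data were examined, except for the alternatives named as added.

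RNA quality was read from the log2 ratio of 3' to 5' control probe sets of Gapdh, beta-actin and hexokinase, compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 12 tests. Alternatives covered quantile normalisation, centring on the array median, no filter and a stricter filter at the 60th percentile, no added constant, eBayes without a trend, array weights, the replicate number as a block, a fit on only the groups compared, the Gapdh ratio as a covariate, each array left out in turn, an estimated correlation for lists, and all probe sets of a gene in lists. Further alternatives were added after the data were seen and are named as such with their effects.

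The procedure was tested on simulated data with known changes in 100 of the 9520 probe sets per size. Of changes of 1 on the log2 scale it recovered 100% for alcohol against isocaloric, 100% for alcohol against control, 97% for isocaloric against control and 99% for trained against naive averaged over diets. For changes of 0.5 these shares were 82%, 80%, 67% and 90%. In the comparison of training effects between the alcohol and isocaloric diets 75% of changes of 1 and 14% of changes of 0.5 were recovered. The adjustment is stricter when fewer probe sets change. The simulated training comparison averaged over diets had 195 calls, against 1 in the data. Recovery shares can therefore be too high for comparisons with few calls, such as those of training. Simulated shifts of 0.3 in the oxidative phosphorylation list and in the endothelial list, in the comparison of alcohol with isocaloric, were both recovered, with 0 of the 26 other lists called. The noise was drawn independently for each probe set, so members of a simulated list were not correlated. The simulation therefore does not show how often lists with correlated members are called falsely. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.09 for alcohol against isocaloric, 0.10 for alcohol against control, 0.11 for isocaloric against control and 0.08 for the averaged training comparison.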

Results

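Transcript levels were compared in the hippocampus of 18 rat samples from 3 diets, alcohol (8 arrays), isocaloric (6) and control (4), of which 10 were trained and 8 naive. Total signal per array ranged from 2.92e+06 to 3.13e+06. Arrays of the same group correlated at 0.952 to 0.985 on the log2 scale, the lowest correlation of any pair was 0.921, and 0 pairs were identical. The 0.952 was between the 2 control naive arrays. Replicate 1 of that group correlated better with all other arrays on average (0.971). The first principal component held 24.6% of the variance and set the control-diet arrays apart. Their scores were 33.6 (naive replicate 2), 15.3 and 15.4 (both trained arrays) and 2.04 (naive replicate 1), against -12.9 to 0.55 on the other 14 arrays. Changes are given as log2 fold changes with their standard errors (SE) and Benjamini-Hochberg adjusted p-values from limma. A statement such as "8 of 8" counts the arrays of the first-named diet, or of the trained state, that lay on that side of the mean of the matching comparison group.

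**Figure D1:**
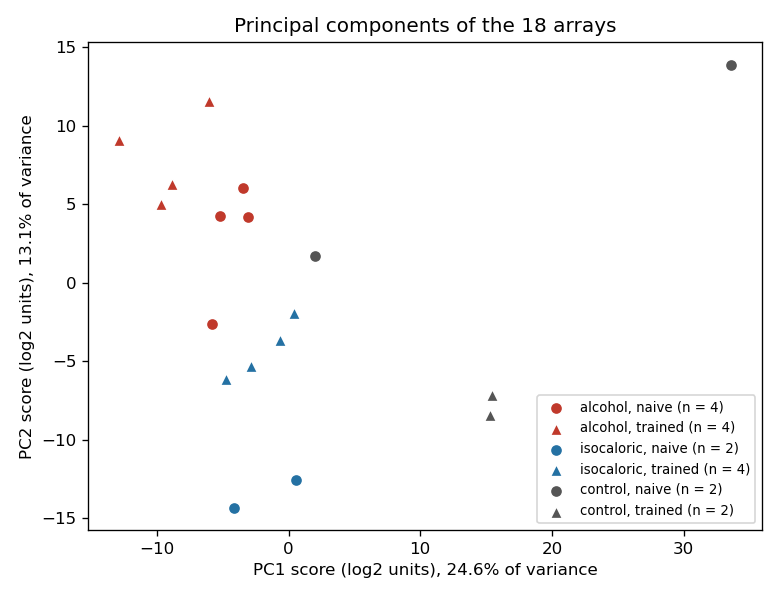
Scores of the 18 arrays on the first (x axis, 24.6% of variance) and second (y axis, 13.1%) principal components, in log2 units. Each point is 1 array, coloured by diet, with circles for naive and triangles for trained samples. Of the control-diet arrays 3 lie to the right, at 15.3 to 33.6 on the first component, and 1 lies at 2.04.

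The comparison of the alcohol with the isocaloric diet asks what alcohol exposure changes beyond calories. Parathymosin (Ptms), a small acidic nuclear protein, rose by 0.81 (SE 0.09, adjusted p = 0.000364, 8 of 8 arrays), from a mean of 9.61 to 10.4. Ptgs2, the activity-inducible cyclooxygenase-2, fell by 0.60 (SE 0.09, adjusted p = 0.00427, 8 of 8). Xpo1, the main nuclear export receptor, fell by 0.61 (SE 0.08, adjusted p = 0.00148, 8 of 8). The ubiquitin-conjugating enzyme Ube2d2 fell by 0.84 (SE 0.11, adjusted p = 0.00155, 8 of 8) and Taf9b, a subunit of the transcription factor TFIID, by 0.88 (SE 0.13, adjusted p = 0.00427, 8 of 8). In all, 291 of 9520 probe sets differed, 140 higher (123 genes) and 151 lower (116 genes) with alcohol, and 4 of them differed by more than 2-fold.

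The kinase Mast3 rose by 1.13 (SE 0.23, adjusted p = 0.0166, 8 of 8). The calmodulin-dependent phosphodiesterase Pde1b rose by 1.04 (SE 0.22, adjusted p = 0.0199, 7 of 8) and Agap3, a GTPase-activating protein for Arf, by 0.85 (SE 0.14, adjusted p = 0.00525, 7 of 8). The calcium sensor hippocalcin (Hpca) rose by 0.53 (SE 0.11, adjusted p = 0.0176, 8 of 8). Increases were also seen for the GABA-B receptor subunit Gabbr1 by 0.52 (SE 0.12, adjusted p = 0.0266, 7 of 8) and the synaptic adhesion protein Clstn3 by 0.47 (SE 0.08, adjusted p = 0.00656, 8 of 8). Brain creatine kinase (Ckb) rose by 0.49 (SE 0.09, adjusted p = 0.00757, 8 of 8) and the actin-nucleating subunit Arpc4 by 0.46 (SE 0.07, adjusted p = 0.00427, 8 of 8). Tecpr1 (0.54), Clpb (0.53) and Isca1 (0.51) also rose. The acylphosphatase Acyp2 fell most, at -1.02 (SE 0.19, adjusted p = 0.00925), and Rapgef4, a cAMP-activated exchange factor for Rap, was at -0.87 (SE 0.13, adjusted p = 0.00427). The translation factor Eif1a fell by 0.65 (SE 0.11, adjusted p = 0.00611) and Fhl2 by 0.74 (SE 0.16, adjusted p = 0.0222), with Pcmtd2, Zbtb38, Wsb1 and Mier1 between -0.70 and -0.60. Each of these falls was seen in 8 of 8 arrays. Second probe sets of Tecpr1 (-0.22, adjusted p = 0.656), Isca1 (-0.14, adjusted p = 0.227) and Xpo1 (0.07, adjusted p = 0.616) had the opposite sign.

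Nuclear-encoded subunits of oxidative phosphorylation rose as a list with alcohol relative to isocaloric: the median of 73 genes was 0.12, camera's adjusted p was 1.40e-10, and the adjusted p = 0.786 with an estimated correlation. In it 4 members rose (Ndufb1 0.45, Ndufc1 0.40, Ndufab1 0.30, Atp5f1d 0.30), 0 fell and 69 did not pass; adjusted over the list alone 8 rose. Of 28 alternatives 17 ended the call of Ndufc1, 14 that of Ndufab1, 11 that of Ndufb1 and 4 that of Atp5f1d. The list median ran from 0.069 with quantile normalisation to 0.19 with median centring. Cytosolic ribosomal proteins had a median of 0.14 over 41 genes (adjusted p = 3.12e-07, and adjusted p = 0.786 with an estimated correlation). Their 1 member up was the laminin-receptor ribosomal protein Rpsa at 0.38 (1 also adjusted over the list alone). Astrocyte markers had a median of 0.14 over 18 genes (adjusted p = 0.0132, and adjusted p = 0.786 with an estimated correlation). The glycolytic enzyme Aldoc rose by 0.36, and adjusted over the list alone 3 rose and 2 fell. The proteasome list had a median of 0.06 over 37 genes (adjusted p = 0.02, and adjusted p = 0.786 with an estimated correlation). Its 1 member past the threshold, Psma1, fell by 0.36, and adjusted over the list alone 1 rose and 1 fell. With quantile normalisation 1 of these 4 lists was called, the others being astrocyte markers (adjusted p = 0.263), ribosomal proteins (median 0.052, adjusted p = 0.172) and proteasome (0.172). The stricter filter on low values (0.142 each) and the hexokinase ratio as a covariate (0.0792 and 0.0958) ended the astrocyte and proteasome calls. The astrocyte list also lost its call without alcohol trained replicate 2 (adjusted p = 0.0561) and the proteasome list without alcohol trained replicate 4 (adjusted p = 0.0576) or without the 4 arrays high in Ttr (0.0569).

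In the 20 measured immediate early genes Ptgs2 and Nr4a1 (-0.33) fell and 0 rose, the same counts as adjusted over the list alone. The list as a whole did not pass (median -0.01, adjusted p = 0.302). Arc (-0.15, adjusted p = 0.468), Egr1 (0.01, adjusted p = 0.956), Bdnf (-0.00, adjusted p = 0.997) and Homer1 (0.03, adjusted p = 0.808) did not pass. The glucocorticoid list (15 genes, median -0.07, adjusted p = 0.596) had 1 rise, metallothionein Mt2A at 0.32, and 1 fall, the glucocorticoid receptor Nr3c1 at -0.40; adjusted over the list alone 2 rose and 3 fell. In the list of ethanol metabolism and antioxidant defence (29 genes, median 0.07, adjusted p = 0.0704) Gpx4, at 0.31, and Mt2A rose, with 5 up and 1 down adjusted over the list alone. The synaptic vesicle list (23 genes, median 0.04, adjusted p = 0.302) had Vamp2 up at 0.30 and Rims1 down at -0.34, with 2 up and 1 down adjusted over the list alone. Of 30 glutamate receptor and postsynaptic genes 0 passed (median 0.04, adjusted p = 0.268). Grin1 was at 0.28 (adjusted p = 0.127), Gria1 at 0.10 (adjusted p = 0.499), Grin2b at -0.10 (adjusted p = 0.765) and Camk2a at -0.20 (adjusted p = 0.522). Axon growth genes (31 genes, median -0.00, adjusted p = 0.956) held Gap43 at 0.01 (adjusted p = 0.957) and Elavl4 at -0.09 (adjusted p = 0.504). Heat shock genes (22, median 0.04, adjusted p = 0.268) had 1 rise, Hsp90ab1 at 0.34.

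No other list passed in this comparison. The adjusted p was 0.268 for neurotrophin and insulin-like growth factor signalling (median -0.09) and for cholesterol synthesis (median -0.10). It was 0.302 for CA1 markers, 0.465 for oligodendrocyte markers, 0.486 for CA3 markers and for DNA methylation and histone modification, and 0.596 for microglia markers. It was 0.886 for thalamus and for interneuron markers, 0.917 for choroid plexus and for meningeal markers, 0.956 for endothelial and mural markers, and 0.974 for dentate granule cell, neuron, GABA and striatum lists. The median, mean and camera direction differed in sign for the axon growth, endothelial, GABA and striatum lists.

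The count of 291 depended on the processing, with 1207 under array weights and 550 in a fit on only the groups compared. This count also depended on single arrays, most on the 2 isocaloric naive arrays. It was 15 without isocaloric naive replicate 2 and 28 without isocaloric naive replicate 1. It was 101 without alcohol naive replicate 3, 143 without alcohol trained replicate 3, 161 without isocaloric trained replicate 3, 179 without alcohol naive replicate 1 and 190 without alcohol naive replicate 2. Of 38 calls under the naming rule, 29 were lost without isocaloric naive replicate 2 and 24 without isocaloric naive replicate 1. Calls often lost included Nr4a1 (20 of 28 alternatives), Rims1 (19 of 28), Clpb (14 of 27) and Mt2A (11 of 28). Ptms, Taf9b, Ube2d2, Xpo1 and Ptgs2 kept theirs under every alternative run, Ptms at an adjusted p of at most 0.00581. The log2 3' to 5' ratio of Gapdh was 0.26 (SD 0.12, n = 8) with alcohol and 0.13 (SD 0.04, n = 6) with isocaloric (exact permutation p = 0.0283, adjusted p = 0.0566). With that ratio as a covariate 25 probe sets passed and 29 of the 38 calls were lost. The split between rises and falls depended on scaling. Of the calls 48.1% were rises as deposited and 49.1% with quantile normalisation. When each array was centred on its median the share was 88.4% (559 up, 73 down). The centring moved the median of all probe sets from -0.02 to 0.06.

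Within naive samples (4 alcohol, 2 isocaloric arrays) 7 probe sets of 6 genes differed, all lower with alcohol. Taf9b fell by 1.23 (SE 0.21, adjusted p = 0.0248), Ube2d2 by 1.09 (SE 0.18, adjusted p = 0.0212) and the serine incorporator Serinc1 by 0.71 (SE 0.11, adjusted p = 0.0212). Xpo1 was lower by -0.69 (SE 0.12, adjusted p = 0.0327) and Fam131a by -0.58 (SE 0.10, adjusted p = 0.0327). Each of these 5 moved in 4 of 4 arrays. Eif3i (0.45, adjusted p = 0.0566), Pde1b (1.67, adjusted p = 0.0598) and Cib1 (0.53) did not pass. Of the lists, oxidative phosphorylation rose (median 0.17, adjusted p = 1.69e-12), with 0 members past the threshold over all probe sets and 4 up adjusted over the list alone. Rises were also seen for ribosomal proteins (0.17, 4.32e-08), astrocyte markers (0.20, 0.00180), proteasome (0.09, 0.00855) and ethanol metabolism and antioxidant defence (0.07, 0.0145). All 5 had an adjusted p = 0.748 with an estimated correlation. The count was 0 without alcohol naive replicate 3 or isocaloric naive replicate 2, 1 without isocaloric naive replicate 1, 3 without alcohol naive replicate 2 and 15 without alcohol naive replicate 1. It was also 0 after median centring, with the replicate block or with the actin ratio, 1 with no filter on low values and 3 without the 4 arrays high in Ttr. Quantile normalisation gave 35 (7 higher, 28 lower), the fit of only the groups compared 15 (3 higher, 12 lower) and array weights 551 (264 higher, 287 lower). Xpo1 lost its call in 12 and Fam131a in 10 of 20 alternatives, Serinc1 in 7 of 20, and Taf9b and Ube2d2 in 7 of 19.

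Within trained samples (4 and 4 arrays) 38 probe sets differed, 29 higher and 9 lower with alcohol. Mast3 rose by 1.43 (SE 0.29, adjusted p = 0.0384), Agap3 by 1.24 (SE 0.17, adjusted p = 0.00457) and Ptms by 1.03 (SE 0.11, adjusted p = 0.000309). Podxl2, an endoglycan, rose by 0.68 (SE 0.13, adjusted p = 0.0291) and the tRNA synthetase subunit Farsa by 0.67 (SE 0.14, adjusted p = 0.0397), in 4 of 4 arrays each. Eif1a fell by 0.75 (SE 0.14, adjusted p = 0.0291), the DNA- and RNA-binding protein Purb by 0.65 (SE 0.12, adjusted p = 0.0254) and Cdca3 by 0.61 (SE 0.12, adjusted p = 0.0378). Ptgs2 fell by 0.58 (adjusted p = 0.0334) and Xpo1 by 0.53 (SE 0.10, adjusted p = 0.0291), again in 4 of 4. Oxidative phosphorylation (median 0.09, adjusted p = 0.00117) and ribosomal proteins (0.08, 0.00576) rose, both with an adjusted p = 0.894 with an estimated correlation. Removing any array lowered the count, to 19, 11, 3 and 23 without alcohol trained replicates 1 to 4, and to 20, 4, 3 and 2 without isocaloric trained replicates 1 to 4. It was 66 after median centring, 81 with array weights, 14 with only the groups compared, 7 with the replicate block, 5 with the Gapdh and 9 with the actin ratio, and 3 without the 4 arrays high in Ttr. Agap3 and Ptms kept their calls under every alternative run, whereas Cdca3 (15), Mast3 and Farsa (14 each), Ptgs2 (12) and Podxl2 (11) lost theirs in that many of 21 alternatives, and Xpo1 in 11 of 22. The difference between trained and naive samples in the effect of alcohol is the interaction given with the training effects.

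The comparison of the alcohol with the control diet gave the longest list of calls. Claudin-5 (Cldn5), the tight-junction protein of brain endothelium, rose by 1.39 (SE 0.08, adjusted p = 9.9e-09, 8 of 8 arrays), from 6.87 to 8.26. The chemokine Cxcl12 rose by 1.33 (SE 0.08, adjusted p = 1.52e-08, 8 of 8), from 5.99 to 7.32. The synaptic adhesion gene Nlgn3 rose by 2.12 (SE 0.35, adjusted p = 0.000756, 8 of 8), from a control mean of 4.72 (SD 1.32, n = 4). The control values of Nlgn3 were 5.89 and 5.83 on the 2 arrays written with fewer digits and 3.67 and 3.49 on the other 2, and its change ran from 1.49 to 3.26 over the alternatives. The signal behind the lower 2 values was close to the added constant of 6.06, so the size of this rise is uncertain. The obligatory NMDA receptor subunit Grin1 rose by 0.69 (SE 0.11, adjusted p = 0.000688, 8 of 8). Camk2a, the calcium/calmodulin-dependent kinase of the postsynaptic density, was lower by -1.82 (SE 0.19, adjusted p = 1.04e-05, 8 of 8) on 1 probe set and higher by 0.95 (adjusted p = 0.0146) on a second, so its probe sets disagreed. In all, 1895 probe sets differed, 1075 higher (846 genes) and 820 lower (667 genes) with alcohol, 45 of them by more than 2-fold.

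Further large rises were the linker histone H1f10 (2.05, SE 0.30, adjusted p = 0.000312), the potassium channel subunit Kcnab2 (1.65, SE 0.25, adjusted p = 0.000479) and the pyruvate dehydrogenase kinase Pdk2 (1.41, SE 0.25, adjusted p = 0.00115). They were followed by Paqr8 1.42, Scaf1 1.39, Tgoln2 1.32, Cdh22 1.30, Gba2 1.27 and Epb41l1 1.24. Large falls included the kinesin heavy chain Kif5b (-0.76, SE 0.11, adjusted p = 0.000312) and the early endosome GTPases Rab5c (-0.75, SE 0.11, adjusted p = 0.000312) and Rab5a (-0.69, SE 0.15, adjusted p = 0.0041). The growth factor pleiotrophin (Ptn) fell by 0.71 (SE 0.17, adjusted p = 0.00835) and Rapgef4 by 0.68 (SE 0.15, adjusted p = 0.00469). Further falls were Chtf8 -0.94, Acyp2 -0.83, Myh1 -0.82, Col15a1 -0.74, Marf1 -0.72 and Cd302 -0.68. Second probe sets of Paqr8 (-0.17), Cxcl12 (-0.01, adjusted p = 0.951) and Rab5a (0.17, adjusted p = 0.178) had the opposite sign and did not pass.

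Endothelial and mural markers rose together with alcohol relative to control. The median of 8 genes was 0.54 (adjusted p = 4.19e-09, and adjusted p = 0.00116 with an estimated correlation). It was the 1 list here past the threshold both ways. In it 7 members rose and 0 fell (8 rose adjusted over the list alone). Among them were the endothelial adhesion molecule Esam at 1.07 (SE 0.11), the VEGF receptor Flt1 at 0.79 (SE 0.12), the pericyte marker Rgs5 at 0.60 (SE 0.12) and the glucose transporter Slc2a1 at 0.44. The synaptic vesicle list rose (median 0.18, adjusted p = 0.000202, and adjusted p = 0.424 with an estimated correlation). Of its 23 members 9 rose and 0 fell, the same as adjusted over the list alone. They included the vesicle GTPase Rab3a at 0.63 (SE 0.08), the active-zone scaffolds Pclo at 0.71 and Bsn at 0.40, and the vesicular glutamate transporter Slc17a7 at 0.39. Glutamate receptor and postsynaptic genes rose (median 0.20, adjusted p = 0.0159, and adjusted p = 0.424 with an estimated correlation). There 7 members were up and 2 down (11 and 2 adjusted over the list alone). Homer3 (0.71), Grm2 (0.63) and Shank3 (0.59) were up and Dlg1 (-0.19) was down. GABA genes rose (median 0.16, adjusted p = 0.0265, and adjusted p = 0.424 with an estimated correlation), the synthetic enzyme Gad2 and the receptor subunit Gabbr2, both at 0.47, passing (4 adjusted over the list alone).

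Oxidative phosphorylation fell in this comparison (median -0.11, adjusted p = 4.55e-05, and adjusted p = 0.681 with an estimated correlation). In the list 12 members fell and 0 rose, the same as adjusted over the list alone, led by Ndufa2 -0.47, Ndufa12 -0.33 and Ndufb11 -0.30. Ribosomal proteins fell (median -0.13, adjusted p = 0.000227, and adjusted p = 0.681 with an estimated correlation). They had 11 members down, such as Rpl24 -0.45 and Rpl13a -0.43, and 1 up, Rpl37a at 0.54 (12 and 1 adjusted over the list alone). Oligodendrocyte markers fell (median -0.15, adjusted p = 0.0476, and adjusted p = 0.681 with an estimated correlation). The 3 down were Pdgfra -0.43, the receptor of oligodendrocyte precursors, the myelin claudin Cldn11 -0.29 and Mbnl1 -0.27 (5 adjusted over the list alone). Mbnl1 is a splicing regulator that is not particular to oligodendrocytes. The other lists did not pass. Their adjusted p ran from 0.0654 for DNA methylation and histone modification (5 members up, among them Hdac4 0.51 and Dnmt1 0.48, and 6 adjusted over the list alone) to 0.878 for astrocyte markers (Vim 0.61 up, 2 members down). Among the immediate early genes (adjusted p = 0.788) Egr1 rose by 0.42 (SE 0.12, adjusted p = 0.02, 8 of 8). Arc (0.28, adjusted p = 0.122) and Bdnf (-0.23, adjusted p = 0.239) did not pass. Gria1 rose by 0.27 (adjusted p = 0.0451, 6 of 8), a call lost in 19 of 27 alternatives, with values from 0.11 to 0.42. Grin2b (0.48, adjusted p = 0.0728), Gap43 (0.17, adjusted p = 0.152), Elavl4 (0.01, adjusted p = 0.943) and Homer1 (0.02, adjusted p = 0.832) did not pass. Nr3c1 fell by 0.42 and the NF-kappaB inhibitor Nfkbia rose by 0.76 in a glucocorticoid list that did not pass (adjusted p = 0.174). Median, mean and camera direction differed in sign for the interneuron, immediate early, neuron, astrocyte and striatum lists.

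The log2 3' to 5' ratio of hexokinase was 0.99 (SD 0.22, n = 8) with alcohol and 1.49 (SD 0.18, n = 4) with control (exact permutation p = 0.00808, adjusted p = 0.0286). For beta-actin it was 0.40 (SD 0.16) and 0.64 (SD 0.09) (exact permutation p = 0.0242, adjusted p = 0.0566). With the actin ratio as an added covariate 315 probe sets and 3 of the lists passed, those being the endothelial, vesicle and glutamate lists, and with the hexokinase ratio 1001 probe sets. Without the 2 arrays written with fewer digits 1 array is left in each control group. These are naive replicate 2, with the highest first-component score (33.6), and trained replicate 1, which is among the 4 arrays high in Ttr. Values from that fit therefore rest on these 2 arrays and cannot part a batch from the control diet. The count was 580 without control naive replicate 2, 899 without control trained replicate 1, 1028 without control trained replicate 2 and 3024 without control naive replicate 1. Of 116 calls under the naming rule 74, 55, 41 and 4 were lost in these. Tgoln2 (17 of 26 alternatives), Cldn11 (15 of 27), Vim (14 of 27) and Dnmt1 (13 of 26) lost theirs in at least every other alternative. Cldn5, Cxcl12, Camk2a, Rab3a, Vamp2, Esam, Flt1, Kif5b and Grin1 were among 18 that kept theirs under every alternative run. Without control naive replicate 2 the glutamate (median 0.072, adjusted p = 0.0767), oxidative phosphorylation (-0.025, 0.360), ribosomal (-0.026, 0.535) and oligodendrocyte (-0.11, 0.382) lists lost their calls, 3 lists remaining. Without the 2 arrays written with fewer digits these medians were 0.32, -0.21, -0.28 and -0.23, and that of the vesicle list 0.29. Without control trained replicate 2, 12 passed. The GABA list lost its call without control naive replicate 1 (adjusted p = 0.0608) or control trained replicate 1 (0.0780). The oligodendrocyte list lost its call also without control trained replicate 1 (0.0527), alcohol trained replicates 2 (0.112) or 4 (0.0668) or alcohol naive replicate 4 (0.180). That list did not pass either with quantile normalisation (0.0681), median centring (0.0595), no filter (0.0647), the stricter filter (0.107), the replicate block (median -0.072, adjusted p = 0.0733) or all probe sets of a gene (median -0.063, adjusted p = 0.218), nor with Gapdh (0.0565), actin (0.129) or Ttr (0.0553) as a covariate. The stricter filter ended the GABA (0.0570) and glutamate (0.117) calls, all probe sets of a gene the glutamate call (0.0534), and the hexokinase ratio (0.385) or leaving out the 4 arrays high in Ttr (0.0540) the GABA call. With the actin ratio the medians were 0.12 for the GABA list, -0.092 for oxidative phosphorylation and -0.085 for the oligodendrocyte list (adjusted p = 0.129 each), and that of the ribosomal list went from -0.13 to -0.010 (0.780). Rises made up 56.7% of calls as deposited, 53.8% with quantile normalisation and 46.4% after median centring, which moved the median of all probe sets from -0.00 to -0.04.

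**Figure D2:**
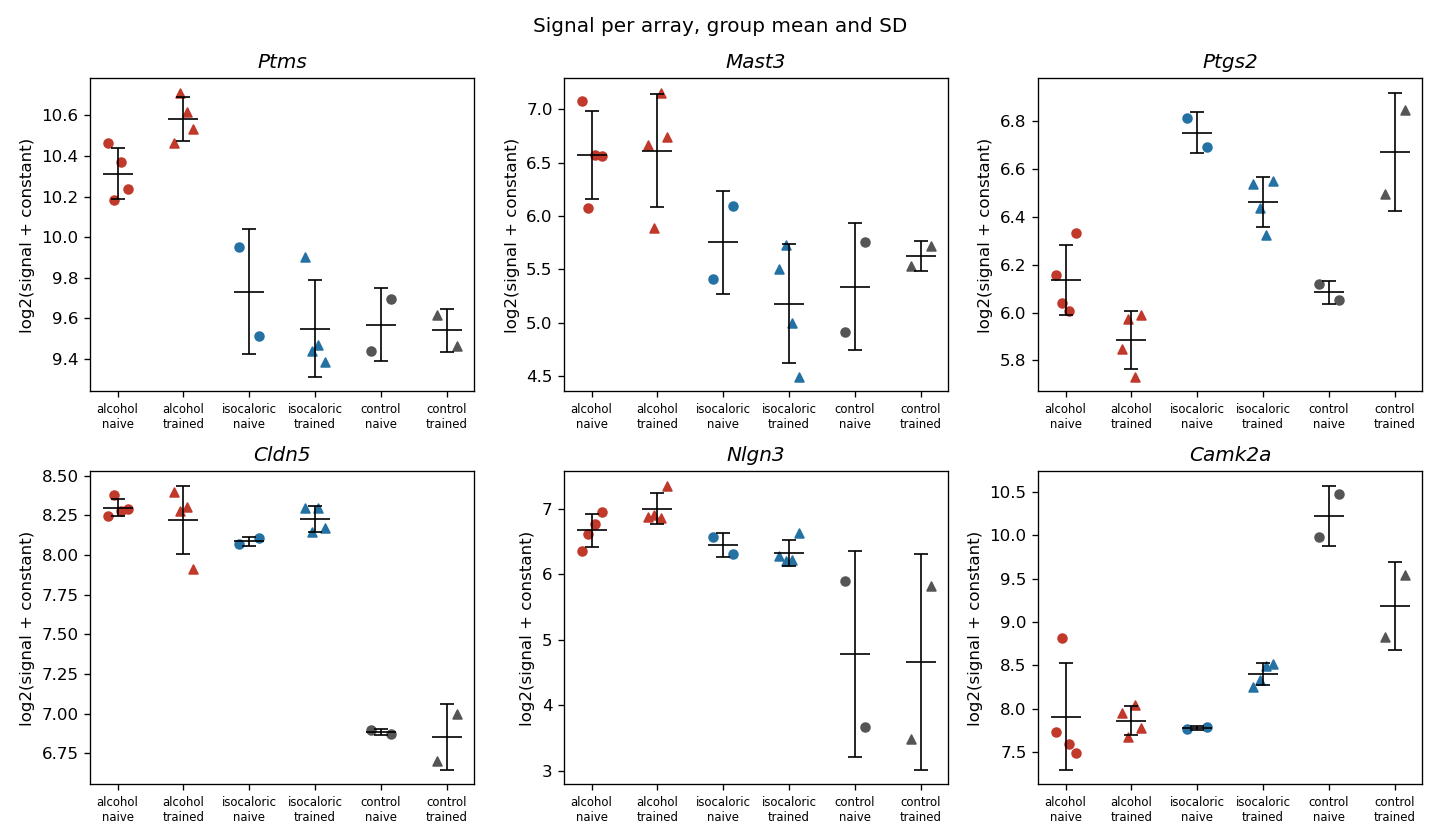
Log2 signal (y axis, log2 of signal plus the constant) of 6 genes in the 6 groups (x axis); points are single arrays, the bar is the group mean and the whiskers the SD. Ptms lies between 10.18 and 10.71 on the 8 alcohol arrays and between 9.39 and 9.95 on the others. Cldn5 lies between 6.70 and 7.0 on the 4 control arrays and between 7.91 and 8.40 on the alcohol arrays.

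Both diets without alcohol also differed from each other, a comparison that holds no alcohol exposure. Isocaloric against control, Cxcl12 rose by 1.45 (SE 0.09, adjusted p = 2.38e-08, 6 of 6 arrays) and Cldn5 by 1.29 (SE 0.09, adjusted p = 7.36e-08, 6 of 6). Nlgn3 rose by 1.67 (SE 0.38, adjusted p = 0.0156, 6 of 6; 1.08 to 2.81 over 24 alternatives, 7 of which ended the call), and the taurine transporter Slc6a6 by 1.07 (SE 0.17, adjusted p = 0.0017, 6 of 6). Camk2a was at -1.62 (SE 0.20, adjusted p = 0.000284, 6 of 6) on 1 probe set and at 0.96 (adjusted p = 0.0413) on a second. In all, 671 probe sets differed, 404 higher (313 genes) and 267 lower (221 genes) with the isocaloric diet, 33 by more than 2-fold. Other large rises were H1f10 1.51, Cdh22 1.32, Zfp414 1.29, Kcnab2 1.26, Leng8 1.23, Pdk2 1.17, Miat 1.10 and Paqr8 1.09. Among the largest falls were the complex I subunit Ndufb1 (-0.74, SE 0.13, adjusted p = 0.0044, 6 of 6), the ATP synthase subunit Atp5f1e (-0.71, 5 of 6) and the complex III assembly factor Uqcc2 (-0.66). The ribosomal genes Rpl13a (-0.66, SE 0.10, adjusted p = 0.00111, 6 of 6) and Rps15 (-0.61, 5 of 6) fell too, along with Chtf8 -0.85, Ly6h -0.71, Marf1 -0.71, Anp32a -0.67, Ociad1 -0.64 and Sec61g -0.60.

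Relative to control, oxidative phosphorylation fell with the isocaloric diet (median -0.23, adjusted p = 2.08e-23, and adjusted p = 0.214 with an estimated correlation). In it 23 of 73 members fell and 0 rose, and adjusted over the list alone 47 fell. Ribosomal proteins fell (median -0.30, adjusted p = 4.34e-17, and adjusted p = 0.330 with an estimated correlation), 16 of 41 down and 0 up (30 adjusted over the list alone). The proteasome list fell (median -0.11, adjusted p = 0.000364, and adjusted p = 0.330 with an estimated correlation). It had 5 members down, such as Psmb10 -0.42 and Psmb4 -0.39 (5 down and 1 up adjusted over the list alone). Ethanol metabolism and antioxidant genes fell (median -0.14, adjusted p = 0.00606, and adjusted p = 0.390 with an estimated correlation). Of these Gpx4 -0.41, Mt2A -0.38 and Txn1 -0.36 were down and the mitochondrial superoxide dismutase Sod2 up at 0.27 (4 down and 2 up adjusted over the list alone). Microglia markers fell (median -0.23, adjusted p = 0.00452, and adjusted p = 0.259 with an estimated correlation) with complement C1qa at -0.51 the 1 member past the threshold either way of adjusting. Heat shock genes (median -0.10, adjusted p = 0.0104, and adjusted p = 0.393 with an estimated correlation) and astrocyte markers (median -0.12, adjusted p = 0.0396, and adjusted p = 0.581 with an estimated correlation) fell. Each had 1 member past the threshold, also adjusted over the list alone: Dnaja1 (-0.37) and the glutamate transporter Slc1a3 (-0.36).

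Endothelial and mural markers rose with the isocaloric diet (median 0.61, adjusted p = 6.30e-12, and adjusted p = 0.000383 with an estimated correlation). Here 8 of 8 members were up (8 adjusted over the list alone), such as Esam 0.91, Flt1 0.88, Rgs5 0.65 and the smooth muscle actin Acta2 0.57. The synaptic vesicle list rose (median 0.16, adjusted p = 0.00178, and adjusted p = 0.387 with an estimated correlation) with Pclo 0.79, Rab3a 0.46 and Bsn 0.39 (3 either way of adjusting). GABA genes rose (median 0.18, adjusted p = 0.0104, and adjusted p = 0.214 with an estimated correlation) with Gad2 0.50, Gabbr2 0.40 and Gabrb2 0.34 (4 adjusted over the list alone). Glutamate genes did not pass as a list (median 0.13, adjusted p = 0.104), with 3 up and 1 down (6 and 1 adjusted over the list alone). Grin1 rose by 0.42 (adjusted p = 0.0437, 6 of 6). Grin2b (0.58, adjusted p = 0.0774), Arc (0.43, adjusted p = 0.06) and Egr1 (0.40, adjusted p = 0.0614) did not pass. Neither did Gria1 0.17, Gap43 0.16, Bdnf -0.23, Elavl4 0.10 and Homer1 -0.01. The remaining lists had adjusted p-values from 0.0617 (neurotrophin signalling) to 0.832, and median, mean and camera direction differed in sign for the neuron and dentate granule cell lists.

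The log2 3' to 5' ratios of Gapdh (0.13 against 0.26, exact permutation p = 0.00476), actin (0.41 against 0.64, p = 0.00476) and hexokinase (1.09 against 1.49, p = 0.00952) were all lower on the isocaloric arrays, with an adjusted p of 0.0286 each. With the actin ratio as an added covariate 38 probe sets and 5 lists passed. Without the 2 arrays written with fewer digits 1 array is left in each control group, so that fit cannot part a batch from the control diet. The count was 81 without isocaloric naive replicate 2, 111 without control naive replicate 2, 168 without control trained replicate 1, and 224 without control trained replicate 2. It was 263 without isocaloric naive replicate 1, 441 without isocaloric trained replicate 4 and 2362 without control naive replicate 1. Cxcl12, Cldn5, Camk2a, Marf1, Rpl13a, Ociad1, Esam and Flt1 were the 8 of 91 calls under the naming rule kept under every alternative run. Of the 91, 71 were lost without isocaloric naive replicate 2. Gabrb2, Txn1, Sod2 and Slc1a3 (18 each), Psmb4 (17), Bsn (16), Grin1 and Psmb10 (15 each) and Gabbr2 (14) lost theirs in that many of 25 alternatives, and Leng8 in 12 of 24. Without control naive replicate 2 the vesicle (median 0.047), ethanol (-0.098) and microglia (-0.11) lists (adjusted p = 0.0547 each) and the astrocyte list (0.411) lost their calls, leaving 6 lists, and the ribosomal and proteasome medians were -0.15 and -0.059. Without control trained replicate 1 the GABA (0.0528), heat shock (0.318) and astrocyte (0.168) lists did, and without isocaloric naive replicate 2 the astrocyte list (0.0694). The astrocyte median was -0.015 with quantile normalisation (adjusted p = 0.487) and -0.031 with all probe sets of a gene (0.362). That list also missed the threshold with median centring (0.0702), the stricter filter (0.208), the replicate block (0.0545), the Ttr covariate (0.0539) and without the 4 arrays high in Ttr (0.212). Heat shock genes lost their call with quantile normalisation (0.220), the hexokinase ratio (0.0664) and without the 4 arrays high in Ttr (0.213), and GABA genes in the latter 2 (0.224 and 0.0614). The Gapdh ratio ended the GABA, astrocyte, ethanol and heat shock calls (0.103 each), and the actin ratio the GABA (0.0835), astrocyte (0.465), ethanol (0.207), heat shock (0.273) and microglia (0.0853) calls. Rises made up 60.2% of calls as deposited, 59.3% with quantile normalisation and 19.1% (232 up, 982 down) after median centring, which moved the median of all probe sets from 0.02 to -0.09. Under either scaling the endothelial list stayed up (past the threshold) and the oxidative phosphorylation and ribosomal lists down.

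Training was compared with the naive state across the 3 diets. Bcr, a GTPase-activating protein for Rac, rose by 0.51 (SE 0.08, adjusted p = 0.0345, 10 of 10 arrays) and was the 1 probe set of 9520 past the threshold. In total 566 probe sets were at an unadjusted p under 0.05 against 476 expected by chance. The next smallest p-values, which did not pass, belonged to Myadm (0.40, adjusted p = 0.438), Trpm7 0.55, Nfia 0.53 and Ube4b 0.32. Downward they belonged to Ramp1 (-0.35, adjusted p = 0.438), Stx12 -0.26, Pdpk1 -0.19 and Hdac11 -0.28. Immediate early genes did not pass as a list (median -0.00, adjusted p = 0.912), with Arc at -0.14 (adjusted p = 0.914), Egr1 at -0.10 (adjusted p = 0.947) and Bdnf at 0.04 (adjusted p = 0.976). Bcr lost its call in 17 of 32 alternatives, 12 of them the removal of a single array, with an adjusted p of up to 0.408. The count was 123 without control naive replicate 1 and 24 without the 2 arrays written with fewer digits.

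A pair of lists passed for training. Choroid plexus markers rose (10 genes, median 0.75, adjusted p = 0.0133, and adjusted p = 0.850 with an estimated correlation). In the list 0 members passed over all probe sets or adjusted over the list alone. Transthyretin (Ttr), the abundant secreted protein of choroid plexus, was at 2.24 (SE 1.02, adjusted p = 0.814, 8 of 10). Enpp2 was at 0.87, Igf2 at 0.77 and Msx1 at 0.43. Ttr was at 12.5 to 12.8 on 4 arrays (alcohol trained replicate 4, alcohol naive replicate 2, isocaloric trained replicate 3, control trained replicate 1) and at 6.10 to 9.57 on the other 14. Without these 4 the list median was -0.053 (adjusted p = 0.999), and without control trained replicate 1 it was 0.28 (adjusted p = 0.654). The call also ended without isocaloric trained replicate 3 (adjusted p = 0.104), control naive replicate 1 (0.0806) or alcohol trained replicate 4 (0.0781), with the replicate block (0.0669) or the hexokinase ratio (0.110), and the Ttr covariate turned the median to -0.18. Glucocorticoid-responsive genes rose (median 0.08, adjusted p = 0.0308, and adjusted p = 0.850 with an estimated correlation), with 0 members past the threshold and 1 adjusted over the list alone. Errfi1 was at 0.33 (adjusted p = 0.756, 9 of 10), Sgk1 at 0.23 (adjusted p = 0.831) and Nfkbia at 0.22. Without single arrays this call ended, at medians of 0.023 to 0.12, for control naive replicate 1 (adjusted p = 0.227), control trained replicate 1 (0.143), isocaloric trained replicate 1 (0.0967), alcohol naive replicate 2 (0.0875), isocaloric naive replicate 1 (0.0759) and alcohol trained replicates 1 (0.0710) and 3 (0.0704). It ended also with the stricter filter (0.0630) and without the 2 arrays written with fewer digits (0.240). With single arrays left out the number of lists past the threshold ran from 0 without control trained replicate 1 to 6 without either control naive array, and it was 7 without the 2 arrays written with fewer digits. The other 25 lists had adjusted p-values of 0.275 to 0.972, and median, mean and camera direction differed in sign for the meningeal and immediate early lists.

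**Figure D3:**
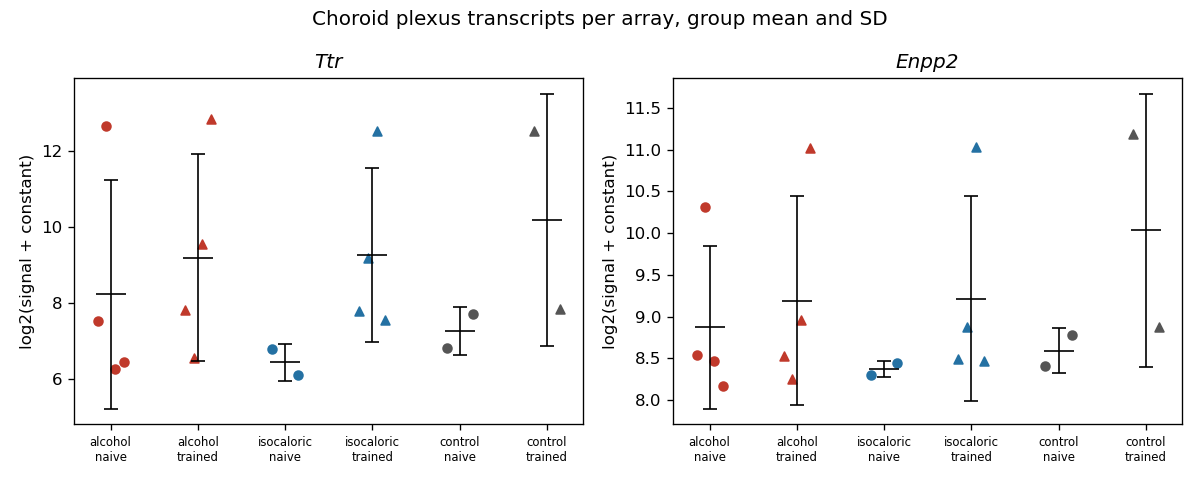
Log2 signal (y axis, log2 of signal plus the constant) of Ttr and Enpp2, transcripts abundant in choroid plexus, in the 6 groups (x axis); points are single arrays, the bar is the group mean and the whiskers the SD. In 4 arrays of 4 groups Ttr lies at 12.53 to 12.84 and in the other 14 at 6.10 to 9.57, and the same 4 arrays are highest for Enpp2.

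Within diets, few probe sets were called for training. In the simulated data 64%, 46% and 25% of changes of 0.5 were recovered in the alcohol, isocaloric and control diets, so smaller changes could be missed. Each simulation held more changed probe sets than were called here, so these shares may be too high. In the alcohol diet (4 and 4 arrays) limma called 0, with 818 at an unadjusted p under 0.05 and a smallest adjusted p of 0.140. Myh1 (0.70, adjusted p = 0.140), Rtel1 0.60, Plpp3 -0.94 and Purb (-0.55, adjusted p = 0.183) had the smallest p-values. Ribosomal proteins rose there as a list (median 0.07, adjusted p = 0.00900, and adjusted p = 0.993 with an estimated correlation). In the isocaloric diet (4 and 2 arrays) limma also called 0, with 678 at an unadjusted p under 0.05. The GTPase Nras was at -1.23 and Fam131a at -0.61 (adjusted p = 0.0660 each), and the sodium channel Scn3a at 0.84. Oxidative phosphorylation (median 0.14, adjusted p = 6.05e-10; 5 up adjusted over the list alone), ribosomal proteins (0.15, 1.35e-09), astrocyte markers (0.13, 0.00233) and ethanol and antioxidant genes (0.08, 0.0269) rose, each with an adjusted p = 0.741 with an estimated correlation. In the control diet (2 and 2 arrays) 1036 probe sets were at an unadjusted p under 0.05, against 476 expected by chance. Of these 3 passed, with an adjusted p of 0.0436 each and 2 of 2 arrays. Myadm rose by 1.00 (SE 0.17), Rpl13a fell by 0.88 (SE 0.14) and Abhd17a fell by 0.69, calls that 13, 10 and 11 of 19 alternatives ended. Ribosomal proteins (median -0.25, adjusted p = 5.98e-13; 1 down, and 4 adjusted over the list alone), oxidative phosphorylation (-0.17, 1.28e-07) and astrocyte markers (-0.17, 0.0352) fell and choroid plexus markers rose (1.46, 0.0352), each with an adjusted p = 0.762 with an estimated correlation. Without control naive replicate 1 the count in the control diet was 698, without control naive replicate 2 it was 31, and without either control trained array it was 1. Each of these fits leaves 1 array in a control group, and without the 2 arrays written with fewer digits 1 array is set against 1. A lone array adds no spread of its own, so such counts rest on the spread of the other groups. The count in the alcohol diet was 1 without alcohol trained replicate 4, and in the isocaloric diet 1 without isocaloric naive replicate 1.

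Whether training acted differently by diet was tested as an interaction. Between the alcohol and isocaloric diets limma called 0 probe sets, with 401 at an unadjusted p under 0.05 and a smallest adjusted p of 0.326. Fam131a (0.68), the heparan sulphate proteoglycan Sdc3 (1.26) and Scn3a (-1.12) had that value. The count was 1 without isocaloric naive replicate 1. The same contrast tests whether the alcohol effect differed between trained and naive samples. Oxidative phosphorylation (median -0.072, adjusted p = 0.000608) and ribosomal proteins (-0.085, 0.0236) were lower in it, both with an adjusted p = 0.950 with an estimated correlation. Across 6938 genes, which are not independent replicates, log2 changes with training correlated between alcohol and isocaloric at r = 0.239 (rho 0.226), between alcohol and control at r = -0.114 (rho -0.151) and between isocaloric and control at r = -0.204 (rho -0.269).

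The alcohol diet was set against both other diets. Of the probe sets called in alcohol against isocaloric and in alcohol against control, 80 were higher in both (15.8 if the lists were independent), 85 were lower in both (13.0 if independent) and 1 was opposite. The alcohol arrays are shared, so the lists are not independent, and the overlap without an effect was not simulated. Over all probe sets 66.2% had the same sign, against 61.9% in simulations without any effect. The 2 sets of log2 fold changes correlated at r = 0.497 across probe sets, and the shared alcohol arrays alone gave 0.367 in simulations without any effect. The covariance was 0.0211 against 0.00456 simulated, and r was 0.340 on average over 36 splits that gave each comparison its own alcohol arrays. Alcohol and isocaloric against control shared 337 higher probe sets (45.6 if independent) and 150 lower (23.0 if independent) with 0 opposite. These comparisons share the control arrays, so they are not independent either, and 74.9% of probe sets had the same sign against 71.2% simulated. They correlated at r = 0.762 against 0.615 simulated, with a covariance of 0.0434 against 0.00908. With the control arrays split between them r was 0.421. The simulated noise was drawn independently for each probe set, whereas deviations of a real array can be shared by many genes. How far these measures range without an effect was therefore not measured, for the split arrays either. The gaps to the simulated values do not show an effect of diet.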

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

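The tests on the high Ttr arrays, the actin covariate and the interaction tests with the control diet were chosen only after the result was seen.

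The 4 control-diet arrays differed from the arrays of both other diets, with 1895 probe sets past the threshold against alcohol and 671 against isocaloric, and 487 called in the same direction in both. RNA quality is argued against as the whole cause, not as part of it: the slope between a control-like score and the hexokinase ratio within the other 14 arrays gave 7.03% of the score difference (95% interval -8.43 to 22.5), and the actin and Gapdh ratios gave -0.251% and 0.750%. With the actin ratio (mean log2 ratio 0.64 with control against 0.40 with alcohol and 0.41 with isocaloric) as a covariate the counts were 315 and 38. Over the 487 probe sets the median change against alcohol went from 0.45 (median SE 0.11) to 0.43 (0.14). Against isocaloric it went from 0.46 (0.11) to 0.43 (0.14). In both, the median error grew by a larger share than the median change fell. A smaller share of vessel cells in the control-diet samples was not settled as a source of the low endothelial markers. The intervals of 6 of 7 other members lay wholly below that of Cldn5 (1.22 to 1.57). Cldn5, the reference, had the largest fold of the list, and markers near background or read in other cells too could show a smaller fold. Unequal folds therefore do not decide the question. Effects of single probe sets remained open, as did the diet itself, which was not tested apart from the handling of these 4 samples: among 388 genes called against both diets, 140 had a second probe set, and 74.3% of these moved the same way (95% interval 66.2 to 81.3), with 35 past the threshold in the same and 6 in the opposite direction.

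Ttr was high on 4 arrays, with a mean of 12.6 against 7.43 on the other 14. Choroid plexus carried over in dissection is a likely source: for 7 of 9 other measured choroid plexus markers the same 4 arrays held the 4 highest values, among them F5 (8.55 against 5.10), Sostdc1 (8.96 against 5.38) and Folr1 (8.23 against 6.29), and for Prlr and Aqp1 they did not. Training or diet is argued against as the whole source, since in 4 of 4 groups that held such an array the other replicates of the same diet and training state lay lower, by 3.27 to 5.15. In the 3 groups with several other replicates this gap exceeded the spread among them, narrowly in the alcohol trained group (3.27 against 3.01). Whether training or diet changed how often such arrays occurred stays open.

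Oxidative phosphorylation and ribosomal lists were called between diets, up in alcohol against isocaloric and down in both diets against control, but with an estimated correlation 0 of these 6 calls remained (adjusted p = 0.786 for both lists, 0.681 for both, and 0.214 and 0.330). Without control naive replicate 2 the alcohol against control calls were also lost (adjusted p = 0.360 and 0.535). The means of both lists also moved together between arrays of the same group (r = 0.914, 95% interval 0.730 to 0.974, permutation p = 0.00036; rho 0.779, permutation p = 0.00541; r = 0.717 without the 2 farthest arrays), as a factor of single arrays that acts on both lists would produce. RNA quality remained open: the correlation within groups of their mean with the actin ratio was 0.426 (95% interval -0.163 to 0.791, rho 0.544, permutation p adjusted over 3 ratios = 0.288), and with that ratio as a covariate the alcohol against control medians went from -0.13 to -0.010 for ribosomal proteins (adjusted p = 0.780) and from -0.11 to -0.092 for oxidative phosphorylation (0.129). With the same covariate both lists kept their calls in alcohol against isocaloric and in isocaloric against control. An effect of diet on mitochondrial and ribosomal transcripts stays among the open explanations, and these arrays do not part it from a factor of single arrays.

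Some values lay far from the other 3 of their group. Chance marks about 1 in 20 groups in this way, and 16 of 237 groups of 4 were marked. Ptms was at 9.90 on isocaloric trained replicate 1 against 9.39 to 9.47 on the others. Xpo1 was at 8.11 on alcohol trained replicate 2 against 7.79 to 7.81. Nlgn3 was at 7.36 on alcohol trained replicate 4 against 6.87 to 6.91, and at 6.63 on isocaloric trained replicate 4 against 6.21 to 6.27. On isocaloric trained replicate 1 Kcnab2 was low at 6.09 (others 6.95 to 7.06) and Zfp414 high at 6.81 (others 6.23 to 6.31). On alcohol naive replicate 2, one of the high Ttr arrays, Col15a1 was at 4.89 (others 5.90 to 6.10) and Ptn at 8.23 (others 9.09 to 9.26), and the mean of the glucocorticoid list was -0.15 (others -0.05 to -0.04). Cd302 was at 5.63 on isocaloric trained replicate 4 (others 5.99 to 6.06), Ndufb1 at 8.81 on isocaloric trained replicate 2 (others 8.58 to 8.62) and Ly6h at 8.52 on alcohol naive replicate 1 (others 8.96 to 8.98). The mean of the astrocyte list was 0.039 on isocaloric trained replicate 2 (others -0.031 to -0.027). The choroid plexus list stood at 1.35 on alcohol naive replicate 2 (others -0.71 to -0.49), 1.87 on alcohol trained replicate 4 (others -0.55 to -0.35) and 2.01 on isocaloric trained replicate 3 (others -0.64 to -0.31).

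Training effects were compared between diets in interaction tests. The count of probe sets was 0 for alcohol against isocaloric, 3 for control against alcohol and 17 for control against isocaloric. The last pair rests on 2 arrays in each control group, and without the 2 arrays written with fewer digits 1 is left in each. Between alcohol and isocaloric the median of the interaction was -0.072 for oxidative phosphorylation and -0.085 for ribosomal proteins, with an adjusted p = 0.950 for both with an estimated correlation. Between control and alcohol these were -0.18 (adjusted p = 2.54e-07) and -0.33 (adjusted p = 3.03e-13), and adjusted p = 0.756 with an estimated correlation. Between control and isocaloric they were -0.30 (adjusted p = 8.07e-13) and -0.42 (adjusted p = 1.86e-16), with the proteasome list at -0.16 (adjusted p = 0.0229) and astrocyte markers at -0.27 (adjusted p = 0.000926), and adjusted p = 0.682 with an estimated correlation.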

How the results depend on the processing

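The covariates for actin, hexokinase and Ttr, the fits without the 4 high Ttr arrays or the 2 arrays written with fewer digits, the split of the control arrays, for lists the Gapdh covariate and the removal of single arrays, and all alternatives for the interactions with the control diet and for the probe sets that set alcohol apart from both diets were chosen after seeing the data. The calls under the naming rule in the 7 comparisons counted next kept their direction under every alternative in which they were measured. Of these, 5 of 38 kept their side of the threshold throughout for alcohol against isocaloric, 18 of 116 for alcohol against control, 8 of 91 for isocaloric against control, 0 of 1 for training, 0 of 3 for training in the control diet, 0 of 5 in naive and 2 of 11 in trained samples. The endothelial list kept its call against control under every alternative. Of 169 named genes that did not pass, 4123 values under alternatives held 82 of the other sign and 163 past the threshold, with 0 both. Fewer arrays or fewer probe sets tested can lower a count by construction; for the other changes the cause was not tested. The signal of dim probe sets near the added constant limits what their fold changes can show.

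Quantile normalisation gave 2 probe sets for training in the isocaloric diet, 35 for alcohol against isocaloric in naive samples and 1 list for alcohol against isocaloric. Centring on the array median gave 632 for alcohol against isocaloric, 1214 for isocaloric against control, 0 for training in the control diet, 0 for alcohol against isocaloric in naive and 66 in trained samples. With no filter on low values the counts were 446 for isocaloric against control, 0 for training, 1 for training in the isocaloric and 0 in the control diet, and 1 for alcohol against isocaloric in naive samples. The stricter filter gave 2 for training in the isocaloric diet, and 2 lists for alcohol against isocaloric, 4 for alcohol against control and 1 for training. Without a trend in eBayes training gave 0, and 0 in the control diet.

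Array weights gave 1207 for alcohol against isocaloric, 979 for alcohol against control, 0 for training, 1 in the alcohol, 46 in the isocaloric and 0 in the control diet, 551 for alcohol against isocaloric in naive and 81 in trained samples, and 1 for the interaction. A fit on only the groups compared gave 550 for alcohol against isocaloric, 172 for isocaloric against control, 1, 2 and 0 for training in the alcohol, isocaloric and control diets, and 15 and 14 for alcohol against isocaloric in naive and trained samples. An estimated correlation left 0 lists for alcohol against isocaloric, 1 for alcohol against control, 1 for isocaloric against control and 0 for training.

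With the replicate number as a block 1138 probe sets passed for alcohol against control, 418 for isocaloric against control, 0 for training, 2 for training in the isocaloric and 0 in the control diet, 0 for alcohol against isocaloric in naive and 7 in trained samples, and 1 list for training. Alcohol against isocaloric gave 213. The interactions of the control diet gave 0 with alcohol and 8 with isocaloric, and 81 of the 165 probe sets apart from both other diets stayed called against both (102 in all). The numbers did not pair the samples: of 36 same-numbered pairs 4 had deviations correlated over 0.1, the median was -0.026 against 0.0081 for other pairs, and 3 arrays correlated best with their own number.

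With the Gapdh ratio as a covariate 25 passed for alcohol against isocaloric, 5 in trained samples, 2 for training in the alcohol diet, and 6 lists for isocaloric against control. The actin ratio gave 315 for alcohol against control, 38 for isocaloric against control, 0 and 9 for alcohol against isocaloric in naive and trained samples, and 3 and 5 lists against control. The hexokinase ratio gave 1001 for alcohol against control, 0 for training, 2 in the alcohol diet, 2 lists for alcohol against isocaloric and 1 for training. The Ttr level gave 0 for training in the control diet and 1 list for training, and turned the choroid plexus median for training to -0.18, since it removes what the list shares with Ttr.

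Without the 4 high Ttr arrays the counts were 44 for alcohol against isocaloric, 568 for alcohol against control, 67 for isocaloric against control, 3 for training, 1, 2 and 1 in the alcohol, isocaloric and control diets, and 3 and 3 for alcohol against isocaloric in naive and trained samples; the choroid plexus median for training was -0.053. Without the 2 arrays written with fewer digits they were 1832 for isocaloric against control, 24 for training and 292 in the control diet, with 12 lists for alcohol against control and 7 for training. Split arrays gave correlations of 0.340 between the alcohol effects and 0.421 between the effects against control.

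Leaving out 1 array in turn, where a lone remaining array is assumed to vary like the other groups, the count ran from 15 to 378 for alcohol against isocaloric (lowest without isocaloric naive replicate 2), 580 to 3024 for alcohol against control (control naive replicates 2 and 1), 81 to 2362 for isocaloric against control (isocaloric naive replicate 2 and control naive replicate 1) and 0 to 123 for training (highest without control naive replicate 1). It ran from 0 to 1 for training in the alcohol diet (1 without alcohol trained replicate 4) and in the isocaloric diet (1 without isocaloric naive replicate 1), 1 to 698 in the control diet (698 without control naive replicate 1), 0 to 15 for alcohol against isocaloric in naive samples (15 without alcohol naive replicate 1), 2 to 23 in trained samples (2 without isocaloric trained replicate 4, 23 without alcohol trained replicate 4) and 0 to 1 for the interaction (1 without isocaloric naive replicate 1). Lists past the threshold ran from 3 to 5 for alcohol against isocaloric, 3 to 12 for alcohol against control (3 without control naive replicate 2, 12 without control trained replicate 2), 6 to 14 for isocaloric against control (6 without control naive replicate 2) and 0 to 6 for training (0 without control trained replicate 1).

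The 3 calls of the interaction of control with alcohol and the 17 of control with isocaloric kept their direction under every alternative, but 0 kept their side of the threshold throughout. Leaving out a control array, or the 2 arrays written with fewer digits, left 1 array in a control group, so counts from those fits rest on the spread of the other groups. Array weights left 0 calls in either interaction. Of the 165 probe sets called for alcohol against both other diets 2 (Ptms and Serinc1) stayed called in both under every alternative, and 0 turned. Without isocaloric naive replicate 2 still 13 were called, without isocaloric naive replicate 1 still 19, with the Gapdh ratio 15, and without the 4 high Ttr arrays 21.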

Other observations

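The interaction tests with the control diet and the alternatives for them and for the probe sets called against both diets were chosen only after the result was seen, as were the genes named against both other diets.

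The alcohol diet stood apart from both other diets at 165 probe sets called in the same direction, of which 13 stayed called in both comparisons without isocaloric naive replicate 2 and 19 without isocaloric naive replicate 1. The genes named here were not tested as groups. Higher with alcohol were the phosphoinositide 3-kinase subunit Pik3r2 (0.39 against isocaloric and 0.83 against control), the muscle-type phosphofructokinase Pfkm (0.40 and 0.85), the growth factor receptor Fgfr1 (0.35 and 0.52), the sensor of oxidative stress Keap1 (0.37 and 0.58) and the Eif4e kinase Mknk2 (0.40 and 0.57). The helicase Eif4a1 (0.32 and 0.35), the elongation factor Eef2 (0.25 and 0.26) and the membrane protein Bsg (0.35 and 0.31) were also higher. Among small GTPases Rab5b (0.44 and 0.55), Rab11b (0.34 and 0.48), Rab1b (0.26 and 0.25), Arf1 (0.23 and 0.22) and Arf5 (0.30 and 0.23) were higher and Rab20 (-0.46 and -0.39) lower. Lower with alcohol were the cap-binding protein Eif4e (-0.51 and -0.51), the bicarbonate transporter Slc4a10 (-0.54 and -0.58), the receptor phosphatase Ptprz1 (-0.52 and -0.52), Akt1 (-0.38 and -0.35) and the AMP-activated kinase subunit Prkaa1 (-0.41 and -0.36). The Camk2 inhibitor Camk2n1 (-0.35 and -0.43), the potassium channel Kcnma1 (-0.30 and -0.42) and the neuronal glycoprotein Gpm6a (-0.34 and -0.30) were lower too. Each of these genes passed the threshold of limma in both comparisons, and 0 of them did so under every alternative.

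The difference in training effect between the control and isocaloric diets, tested with 2 arrays in 3 of its 4 groups, was largest for Pde1b (-2.96, SE 0.53, adjusted p = 0.0288) and Nras (1.98, SE 0.32, adjusted p = 0.0228). Taf9b (1.65), the neuronal regeneration protein Nrep (1.46), Srgn (1.34), the La antigen Ssb (1.34), St6galnac3 (1.19), the histone methyltransferase Ash1l (1.13), Plcl1 (1.11), Eml1 (1.07) and 1 unnamed probe set changed more upward with training in the control diet. Ext1 (-1.31), which builds heparan sulphate, Bola2 (-1.02), Rpl13a (-0.97), Abhd17a (-0.91), the histone deacetylase Hdac5 (-0.84) and Eif3i (-0.75) changed more downward. Between the control and alcohol diets Alkbh5, an RNA demethylase, differed by 0.97 (adjusted p = 0.0351), Kctd17 by -0.78 (adjusted p = 0.0471) and Abhd17a by -0.87 (adjusted p = 0.0351). Of these 20 calls 0 passed under every alternative, and without isocaloric naive replicate 2 the count for control against isocaloric was 0.

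Arrays were also regrouped at random. The splits treat arrays as independent and do not test a factor shared by the arrays of a diet. Of 1050 possible splits for alcohol against isocaloric 100 were run. The highest of the other splits gave 59 against the real 291, and 1 of 100 was as large, the real one. A random grouping of the arrays is thus an unlikely source of that count, although it cannot be excluded. For alcohol against control 1 of 100 was as large (1895, highest other 1236), and for isocaloric against control 1 of 90 (671, highest other 313). In trained samples alcohol against isocaloric gave 38 and the highest other split 1, with 1 of 35 as large. Chance cannot be excluded for training averaged over diets, where 29 of 100 splits gave at least the real count of 1 (highest other 2). For training in the alcohol diet the real count was 0 and the highest other 0, so that all 35 of 35 splits had to give at least as many and nothing was tested.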
